A study of Bos taurus with 32 samples.

How the data were processed

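RNA from the left kidney of grazing beef steers (Bos taurus) was measured on 32 arrays, 8 in each of 4 groups and 4 per group in each of 2 batches. Per the labels' protocols, mid-cross sections of the kidney were frozen, total RNA was extracted with TRIzol, and cRNA was labelled with biotin. The deposited values are log2 levels per probe set, from 1.01 to 14.48, which the authors had already summarized and brought close to a common distribution. The scale was read from the values. GCOS 1.2 and Partek are named per the submitters' processing notes, and the summarization and normalization methods are not given in the sources used here. Array medians ran from 6.22 to 6.32 and correlations between arrays from 0.949 to 0.987. Groups, replicate numbers and batches came from the sample titles, and replicate numbers were unique over the 32 arrays, so no arrays were paired across groups.

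The table held 26773 probe sets without missing values. Of these, 18457 had 1 gene symbol in the platform annotation, 688 had several and 7628 had none, and 183 repeated the values of an earlier probe set. The 1-symbol probe sets covered 18010 genes. Control probe sets could not be told apart in the annotation used here, so all 26773 were tested, although the plan had been to leave controls out. No genome coordinates were used here. A gene was represented by its 1-symbol probe set with the highest mean over all arrays.

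Each probe set was fitted with limma 3.58.1 in R 4.3.3 with a mean per group and a batch term, which left 27 residual degrees of freedom. The contrasts were the main effects of selenium form and of endophyte, their interaction and the 4 simple effects. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all 26773 probe sets, and 0.05 was the threshold. Gene lists, 36 for functions and 17 for cell types, were tested with camera at a preset correlation of 0.01, adjusted over the 53 lists, and with an estimated correlation and fry as alternatives. Members were also adjusted over the list alone, without correction for the number of lists. Of 1332 list entries, 1160 were measured. Correlations across arrays were tested by permutation. Plots were drawn with Python 3.11.15.

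Groups, tests, gene lists, the rule for named genes and the other settings listed last were fixed before the data were examined. For each main effect, the rule took 10 genes per direction, filled up by smallest unadjusted p where fewer passed. For the interaction and the simple effects it took 5 per direction, and for each list up to 4 members of smallest p. All selenoproteins could be named. For named genes, counts of arrays beyond the mean of the other side only describe the values, since the genes were picked by p on the same arrays. The segment markers on the 2 arrays with little proximal tubule signal, and MX1 and ISG15, were chosen after their values were seen.

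The fit was tested on simulated data with the spread of the real arrays, for selenium form over 26773 probe sets with 50 changed at each size. It recovered 17 of 50 at a log2 difference of 0.25, 45 at 0.5, 48 at 0.75 and 48 at 1, with 4 false calls. Because 200 probe sets were changed at once, these rates may overstate the recovery where only a few differ. A simulated shift of 0.2 in 1 list was called with the preset and with the estimated correlation, with 0 other lists called. Genes were simulated as independent, so this could not show how often lists of correlated genes are called without a difference.

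The other settings were quantile normalization of the deposited values, leaving out the dimmest 40% of probe sets, no batch term, each batch alone, array weights, a covariate for tissue composition, no variance moderation, a trended and robust variance prior, only the 2 groups compared, and the mean of all probe sets of a gene. The composition covariate was the difference between the standardized levels of the proximal tubule list and of the 2 collecting duct lists. Leaving out ISeNTE replicate 20 and MIXNTE replicate 32, and leaving out each of the 32 arrays in turn for the counts, the lists called and the members that passed over their list alone, were added after seeing the data.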

Results

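Kidney RNA was measured on 32 bovine arrays, each hybridized with biotin-labelled cRNA made from a frozen cross section of the left kidney of a grazing beef steer. The arrays fell into 4 groups of 8 in a factorial arrangement of selenium form and tall fescue type. ISe stands for inorganic selenium and MIX for a mixture of inorganic and organic selenium. TE stands for fescue infected with a toxic endophyte, a fungus whose ergot alkaloids constrict blood vessels, and NTE for fescue with a non-toxic endophyte. These readings come from the series title and from what is known of the study. Each group (ISeNTE, ISeTE, MIXNTE and MIXTE) had 4 arrays in each of 2 batches. The labels used here do not state outright that each array is a different steer, so p-values measure the spread between these samples. The values were log2 levels of 26773 probe sets, and the number of arrays limits their precision. For the median probe set, the 95% confidence interval of a main effect reached 0.15 on the log2 scale to either side, and that of a difference between 2 single groups 0.21.

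Markers of the nephron segments were not at one level on every array. Markers of the proximal tubule, the cortical segment that reabsorbs glucose, amino acids and phosphate, were far lower on ISeNTE replicate 20 and MIXNTE replicate 32 than on the other 30 arrays. Averaged over the 24 measured markers, these arrays deviated from the mean of all 32 arrays by −3.37 and −2.65 log2 units, whereas the lowest of the other 30 deviated by −0.22. The organic anion transporter SLC22A8 measured 5.90 and 6.22 on these arrays against 10.93 ± 0.26 (SD) on the other 30, and the creatine synthesis enzyme GATM measured 6.16 and 6.63 against 11.12 ± 0.51. The thiazide-sensitive cotransporter SLC12A3 of the distal convoluted tubule measured 5.73 and 5.63 against 10.13 ± 0.35. Among markers of the inner kidney, the urothelial UPK1B measured 8.05 and 8.05 against 5.74 ± 0.85, above the highest of the other 30 at 7.20. The urea transporter SLC14A2 measured 10.18 and 9.38 against 7.36 ± 1.05, and the highest of the other 30, at 9.88, exceeded its level on MIXNTE replicate 32. The thick limb marker UMOD, at 12.70 and 12.52, was inside the range of 11.14 to 12.97 of the other 30 arrays. Both arrays belonged to NTE groups, 1 under each selenium form and 1 in each batch. Each comparison was therefore also run without them.

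**Figure D1:**
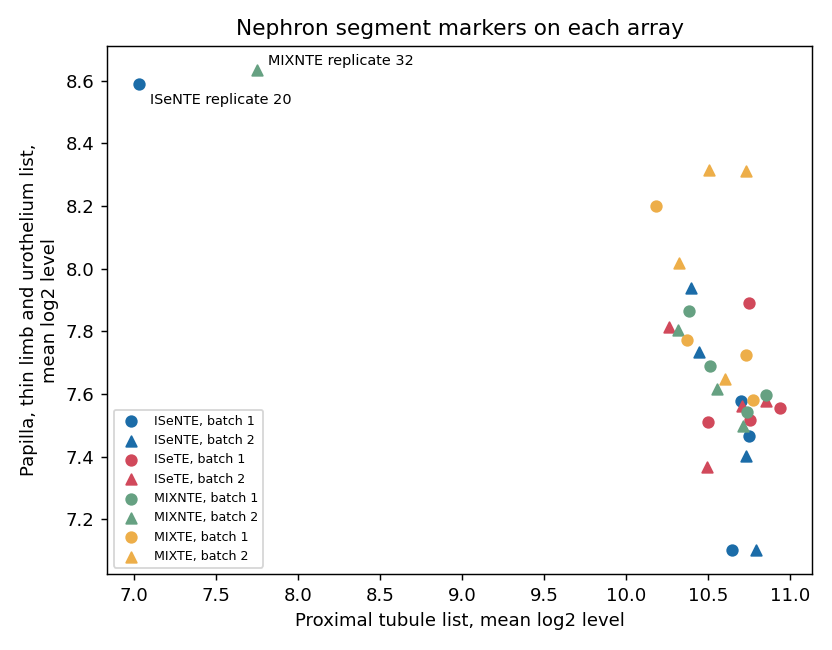
Mean log2 level of the proximal tubule list (horizontal axis) and of the papilla, thin limb and urothelium list (vertical axis) on each of the 32 arrays. Each point is 1 array, colours mark the 4 groups and point shapes the 2 batches. ISeNTE replicate 20 and MIXNTE replicate 32 lie apart from the other 30 arrays.

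The comparison of MIX with ISe asked whether the form of supplemented selenium altered kidney transcripts. No gene passed the test for a difference between the forms. The actin-binding protein gene NEXN (probe set 12843193) measured 7.33 ± 0.24 under MIX and 6.97 ± 0.28 under ISe (SD, n = 16 each), a log2 difference of 0.36 ± 0.08 (SE). It lay above the ISe mean on 15 of 16 MIX arrays (limma, adjusted p = 1). NXPE2 measured 4.60 ± 0.73 against 3.85 ± 0.39, a difference of 0.75 on the log2 scale. Higher values under MIX were also seen for LRRC38, PIK3R4 of the class III phosphatidylinositol 3-kinase, MAMDC2, GCNT3, RUBCNL, LOC515333, TMEM131L and the T-type calcium channel gene CACNA1G, with log2 differences from 0.14 to 0.46. Lower values under MIX, by −0.33 to −0.13, were seen for the ubiquitin ligase gene MARCHF1, SCEL, N6AMT1, HSF2BP, MAGEB4, TMCO4, ZNF3, the histone deacetylase gene HDAC11, MVB12B and NUGGC. SCEL was dim, at 3.07 against 3.28. Adjusted p was 1 for each of these 20 genes. In all, limma called 0 of 26773 probe sets at an adjusted p under 0.05, with 518 higher and 456 lower at an unadjusted p under 0.05, where chance alone would give about 1339. The linear model without variance moderation, and the moderated fit with a trended and robust prior, also called 0, as did the fit without the 2 arrays with little proximal tubule signal and the fits within each batch.

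Selenoproteins, which carry selenium as selenocysteine, are the genes most directly tied to selenium supply, and all 25 listed were measured. None passed the test for selenium form, either over all probe sets or adjusted over the list alone (smallest adjusted p = 0.32). The plasma glutathione peroxidase gene GPX3 measured 13.02 ± 0.40 under MIX and 12.99 ± 0.62 under ISe (SD, n = 16 each). GPX1, the cytosolic glutathione peroxidase, differed by −0.09 (95% confidence interval −0.21 to 0.02), and the selenium transport protein gene SELENOP by −0.05 (−0.28 to 0.18). GPX4 measured 8.90 ± 0.16 under MIX and 8.90 ± 0.24 under ISe, and the sign of its difference turned with quantile normalization. The signs for GPX3 and DIO1 turned without the 2 arrays with little proximal tubule signal. The thyroid hormone deiodinase gene DIO2 had a log2 difference of 0.32 (0.03 to 0.61), TXNRD3 of 0.12 (0.01 to 0.24) and SELENOH of 0.10 (0.01 to 0.19), with unadjusted p of 0.0292, 0.0333 and 0.0384. DIO2 measured 5.87 on MIXNTE replicate 32, 1 of the 2 arrays with little proximal tubule signal, and at most 5.07 on the other MIXNTE arrays. In the whole list 12 genes were higher and 13 lower under MIX. The median of the list lay below 0, its mean lay above 0 at 0.01, and the set test pointed upward without passing (camera, adjusted p = 0.817, and adjusted p = 0.859 with an estimated correlation).

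**Figure D2:**
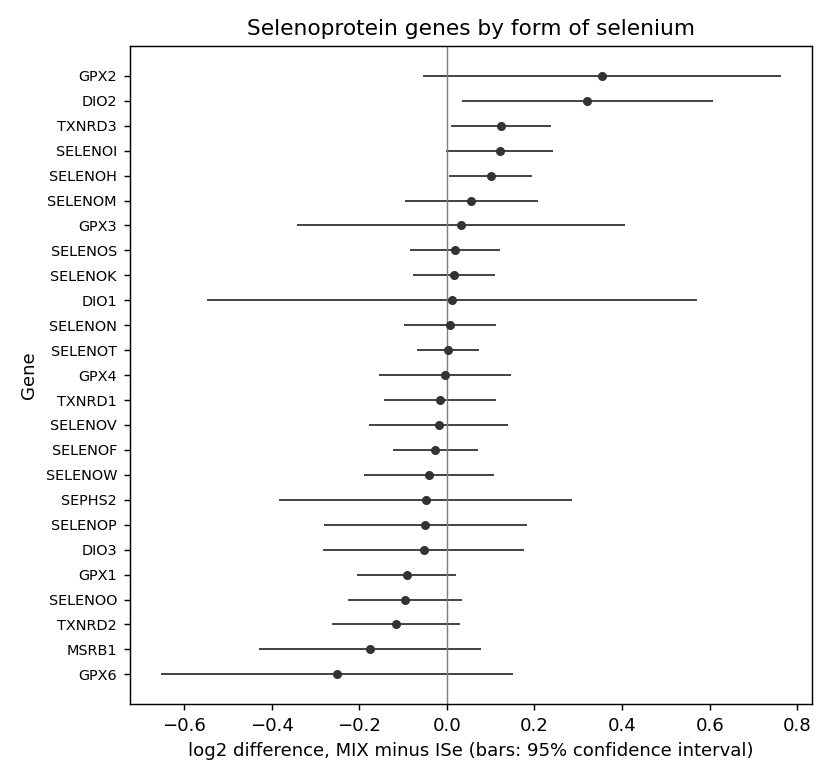
Log2 difference between MIX and ISe (horizontal axis) for each of the 25 selenoprotein genes (vertical axis), averaged over TE and NTE. Points are limma estimates from 32 arrays and bars their 95% confidence intervals. The intervals of 3 of the 25 genes exclude 0.

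As groups, the genes of oxidative phosphorylation were lower under MIX, 61 of the 63 measured, with a mean log2 difference of −0.06. The mitochondrial subunit genes COX7A2, NDUFA8 and UQCR11 differed by −0.10, −0.11 and −0.13. Genes of fatty acid oxidation were lower for 25 of 31 measured members, among them ANGPTL4 at −0.28, HADH at −0.12 and FABP3 at −0.15. Immediate early genes, which respond within minutes to stimulation, were higher for 24 of 30, with IER5 at 0.17, FOSB at 0.25 and NR4A3 at 0.28. Inflammation genes were higher for 24 of 30, with NFKBIZ at 0.21, CCL5 at −0.22 and CXCL8 at 0.16. Markers of the papilla and urothelium were higher for 11 of 15, with UPK1B at 0.91, the aldose reductase gene AKR1B1 at 0.67 and S100A4 at 0.59. Smooth muscle markers were higher for 11 of 13, with CNN1 at 0.32, TAGLN at 0.22 and MCAM at 0.09. Interferon response genes were lower for 26 of 27, with CXCL9 at −0.42, CXCL10 at −0.50 and OAS1Y at −0.60. No member of these 7 lists passed adjustment over the list alone. With a preset correlation between genes, camera called these 7 of 53 lists, with adjusted p from 2.46e-10 to 0.0444. With an estimated correlation it called 0 (smallest adjusted p = 0.859), and fry called 0. Between 8 and 13 of the 16 MIX arrays lay beyond the ISe mean in the direction of each list. In reverse, 6 of the 16 ISe arrays lay above the MIX mean for interferon, and 12 to 14 lay on the ISe side of it for the other lists. The shifts were uneven between the batches. Of the 2 arrays with little proximal tubule signal, ISeNTE replicate 20 was in batch 1 and MIXNTE replicate 32 in batch 2. They lay on opposite sides of this contrast, which could widen the unevenness for the lists other than interferon. Mean differences in batch 1 and batch 2 were 0.00 and −0.13 for oxidative phosphorylation, 0.01 and −0.11 for fatty acid oxidation, −0.08 and 0.26 for immediate early genes, 0.35 and −0.84 for interferon genes, −0.05 and 0.25 for smooth muscle, 0.10 and 0.42 for papilla, and 0.05 and 0.08 for inflammation. On ISeNTE replicate 20 and MIXNTE replicate 32, papilla markers deviated by 0.85 and 0.90 from the mean of all arrays. Smooth muscle deviated by 0.42 and 0.25, fatty acid oxidation by −0.43 and −0.56 and oxidative phosphorylation by −0.24 and −0.30. These directions match those under MIX, so a different share of cortex could not be told apart from selenium form. Papilla stayed called without these 2 arrays (0.27, camera adjusted p = 0.00446). Without the 2 arrays with little proximal tubule signal the interferon list was no longer called (−0.11, adjusted p = 0.472). Of these, ISeNTE replicate 20 was itself high for interferon genes, deviating by 1.88 from the mean of all arrays, and MIXNTE replicate 32 by −0.42. When each of the 32 arrays was left out in turn, oxidative phosphorylation was called every time. The other calls ended on leaving out any 1 of 3 arrays for immediate early genes, 9 for fatty acid oxidation, 9 for papilla, 11 for interferon, 13 for smooth muscle and 20 for inflammation. MIXNTE replicate 32 alone ended 6 of the 7 calls. Without it the mean differences were −0.01 for fatty acid oxidation, 0.06 for immediate early genes and 0.04 for inflammation, against −0.05, 0.09 and 0.07 on all arrays. Fatty acid oxidation was −0.08 without ISeNTE replicate 20, and immediate early genes were 0.06 without MIXNTE replicate 14 and 0.05 without MIXTE replicate 23. Smooth muscle was 0.06 without MIXTE replicate 4, against 0.10. The interferon difference of −0.24 became −0.16 without ISeNTE replicate 5, −0.14 without ISeNTE replicate 11, −0.13 without ISeNTE replicate 20 and −0.40 without MIXNTE replicate 25.

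The comparison of TE with NTE asked what grazing toxic fescue did to kidney transcripts. No gene passed the test here either, though the smallest adjusted p was lower. SYNGR1 (probe set 12861173) measured 8.21 ± 0.18 on TE and 8.45 ± 0.11 on NTE (SD, n = 16 each), a log2 difference of −0.23 ± 0.05 (SE), and lay below the NTE mean on 15 of 16 TE arrays (adjusted p = 0.261). LOC534913 had a difference of 0.23 ± 0.05, lying above the NTE mean on 15 of 16 TE arrays (adjusted p = 0.261). The mitochondrial ADP/ATP carrier gene SLC25A4 differed by −0.44, with 9.28 ± 0.30 on TE and 9.72 ± 0.31 on NTE, and lay below the NTE mean on 16 of 16 TE arrays. RBM3, a cold-inducible RNA-binding protein, differed by −0.31, the gap junction gene GJC1 by −0.28, HAUS4 by −0.27 and the retinol saturase gene RETSAT by −0.36. KLHL26, SERPINA3-7, RGS20 and MIR2304 were also lower in value. SERPINA3-7 (2.00 against 2.36) and MIR2304 (2.47 against 2.70) were dim, as the dimmest 40% of probe sets had means up to 5.73. Higher values on TE were seen for the thiamine transporter gene SLC19A3 (0.47), SPIDR (0.29), the collagen prolyl hydroxylase subunit gene P4HA1 (0.26), RAB23, NEK4, HOOK2, NR6A1, FLOT1 and DPAGT1, which starts N-linked glycan assembly. Apart from SYNGR1 and LOC534913 these genes had an adjusted p of 0.39. In all, limma called 0 of 26773 probe sets, with 818 higher and 819 lower at an unadjusted p under 0.05. The unmoderated model and the trended and robust fit also called 0, as did the fit without the 2 arrays with little proximal tubule signal. With MIXTE replicate 23 alone left out, 1 probe set without a gene symbol was called (adjusted p = 0.0465).

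Among gene groups, markers of smooth muscle and pericytes were lower on TE for 13 of 13 measured genes. The mean of the list was 7.53 ± 0.24 on TE and 7.74 ± 0.19 on NTE (SD, n = 16 each), a difference of −0.21 ± 0.07 (SE). The pericyte and endothelial adhesion gene MCAM differed by −0.19, the PDGF receptor gene PDGFRB by −0.17 and the tropomyosin gene TPM2 by −0.25. The list lay below the NTE mean on 14 of 16 TE arrays, and its difference was −0.22 in batch 1 and −0.20 in batch 2. Camera called it with the preset correlation (adjusted p = 4.22e-07) but not with an estimated one (p = 0.0056, adjusted p = 0.297 with an estimated correlation). Without the 2 arrays with little proximal tubule signal the difference was −0.18.

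**Figure D3:**
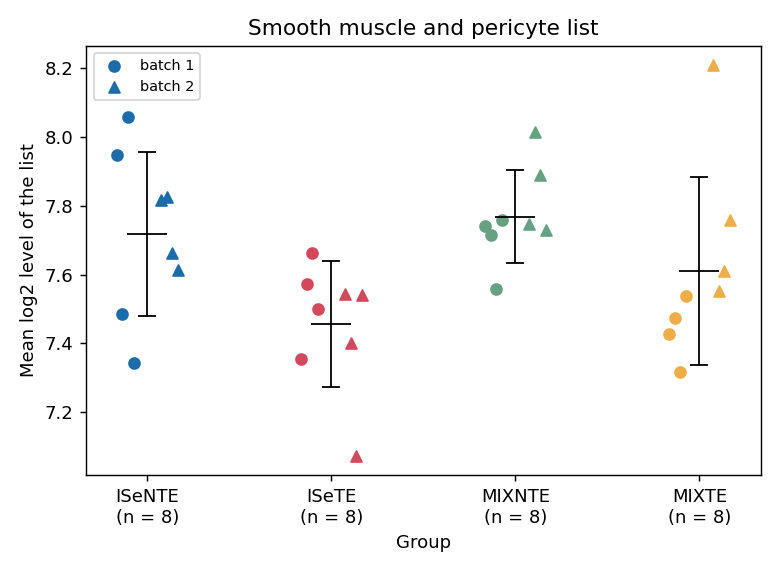
Mean log2 level of the 13 measured smooth muscle and pericyte genes (vertical axis) on each array of the 4 groups (horizontal axis). Points are arrays, shapes mark the batches, and the bars show the mean ± SD of 8 arrays, lower in both TE groups than in both NTE groups.

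Genes of the stress response of the endoplasmic reticulum were higher on TE for 23 of 26 measured (camera, adjusted p = 1.42e-05, and adjusted p = 0.703 with an estimated correlation). Adjusted over the list alone, 2 of them passed, the disulfide isomerase gene PDIA4 (log2 difference 0.28, adjusted p = 0.0133) and the chaperone gene HSP90B1 (0.20, adjusted p = 0.0483), while DNAJC3 differed by 0.14. Here and below, this adjustment took no account of the 53 lists, so members of some lists can pass by chance. Over all probe sets neither passed, and HSP90B1 no longer passed over the list alone with any 1 of 21 arrays left out (adjusted p up to 0.0992). Nor did HSP90B1 pass without the 2 arrays with little proximal tubule signal, where its difference was 0.18 (adjusted p = 0.132). Heat shock genes were higher for 16 of 18, with HSPB1 at 0.19, HSPB8 at 0.17 and HSP90AB1 at 0.23 (for the list, adjusted p = 0.703 with an estimated correlation). Proteasome genes were lower for 27 of 30, with PSMD14 at −0.16, PSMC5 at −0.09 and PSMC1 at −0.05 (for the list, adjusted p = 0.703 with an estimated correlation). Oxidative phosphorylation genes were lower for 53 of 63, with UQCRB at −0.15, NDUFS8 at −0.12 and ATP5MC1 at −0.14 (for the list, adjusted p = 0.787 with an estimated correlation). Genes of cholesterol synthesis were lower for 17 of 23 (adjusted p = 0.703 with an estimated correlation). INSIG1, which holds back the sterol-sensing transcription factors, passed over the list alone (−0.26, adjusted p = 0.0327), and SQLE and FDFT1 differed by −0.35 and −0.18. INSIG1 no longer passed with any 1 of 12 arrays left out (adjusted p up to 0.07) or without the 2 arrays (−0.23, adjusted p = 0.109). Markers of macrophages and dendritic cells were lower for 15 of 19, with CD163 at −0.49, ITGAM at −0.19 and C1QA at −0.32 (for the list, adjusted p = 0.737 with an estimated correlation). Their mean difference of −0.15 became −0.09 without ISeNTE replicate 11, which ended the call (adjusted p = 0.0881). Interferon response genes were lower for 26 of 27, with IFIT2 at −0.36, IFIT3 at −0.42 and STAT2 at −0.14 (for the list, adjusted p = 0.835 with an estimated correlation). Outside the called lists, P4HA1 passed over the hypoxia list alone (adjusted p = 0.00298). It lay above the NTE mean on 16 of 16 TE arrays, a count that adds no support, since its small p came from the same arrays. In the metal handling list the transferrin receptor gene TFRC (−0.31) and the zinc and iron transporter gene SLC39A14 (0.26) passed, each with an adjusted p of 0.0324 over the list alone. They no longer passed with any 1 of 10 and any 1 of 11 arrays left out, respectively (adjusted p up to 0.0683).

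Markers of the proximal tubule were higher on TE for 24 of 24, by a mean of 0.38, with CYP27B1 at 0.56, SLC7A9 at 0.53 and PCK1 at 0.50 (for the list, adjusted p = 0.737 with an estimated correlation). Those of the distal convoluted and connecting tubule were higher for 10 of 10, by a mean of 0.29, with TRPV5 at 0.35, SLC8A1 at 0.49 and KCNJ16 at 0.13 (for the list, adjusted p = 0.54 with an estimated correlation). Without the 2 NTE arrays with little proximal tubule signal both calls ended, as the proximal tubule difference was −0.02 (adjusted p = 0.421) and the distal one 0.13 (adjusted p = 0.0702), and so did the calls of the interferon list (−0.11, adjusted p = 0.178) and of cholesterol synthesis (adjusted p = 0.0636). Of these arrays, ISeNTE replicate 20 was itself high for the interferon list, 1.88 above the mean of all arrays. The proximal tubule difference was 0.15 without ISeNTE replicate 20 alone and 0.20 without MIXNTE replicate 32 alone. Oxidative phosphorylation moved the other way, from −0.05 to −0.09 without the 2 arrays and to −0.07 without ISeNTE replicate 20 alone. Without the 2 arrays camera gave it an adjusted p of 6.23e-20, but with the preset correlation, which takes genes as nearly independent. An estimated correlation was not tried there, and on all arrays it called 0 lists. The interferon call ended with any 1 of 9 arrays left out. Its difference of −0.20 became −0.04 without MIXNTE replicate 25, −0.09 without ISeNTE replicate 20, −0.09 without ISeNTE replicate 11 and −0.11 without ISeNTE replicate 5. Mean differences in batch 1 and batch 2 were 0.42 and 0.35 for the proximal tubule, 0.27 and 0.32 for the distal tubule, 0.10 and 0.10 for endoplasmic reticulum stress, 0.11 and 0.13 for heat shock and −0.04 and −0.06 for the proteasome. They were −0.07 and −0.03 for oxidative phosphorylation, −0.10 and −0.03 for cholesterol synthesis, −0.10 and −0.20 for macrophages and −0.11 and −0.28 for interferon genes. In all, camera called 10 of 53 lists by endophyte with the preset correlation, 4 higher and 6 lower, with adjusted p from 4.22e-07 to 0.0141. With an estimated correlation it called 0 (smallest adjusted p = 0.297), with an unadjusted p under 0.05 for 2 lists, and fry called 0 (smallest adjusted p = 0.185). Between 11 and 15 of the 16 TE arrays lay beyond the NTE mean in the direction of each list. The count was 15 only for the proximal and distal tubule lists, whose NTE means were lowered by the 2 arrays with little proximal tubule signal. In reverse, 4 of the 16 NTE arrays lay above the TE mean for interferon. For the proximal tubule 8 lay below it, and for the other lists 10 to 15 lay on the NTE side of it. For selenoproteins, 0 of 25 passed over the list alone, with 15 higher and 10 lower on TE.

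The interaction asked whether the difference between MIX and ISe depended on the fescue. The gene with the smallest p was ERBB3 (probe set 12869248), a receptor tyrosine kinase of the epidermal growth factor family. It measured 7.54 ± 0.31 in ISeNTE, 7.99 ± 0.21 in ISeTE, 7.92 ± 0.20 in MIXNTE and 7.49 ± 0.20 in MIXTE (SD, n = 8 each). Its interaction was −0.87 (95% confidence interval −1.21 to −0.53) and did not pass (limma, adjusted p = 0.3). BCAR4, EXD3, FBXL12 and the IgM receptor gene FCMR had interactions from −0.64 to −0.32. KLHL41, NXPE3, MIR376D, LOC781494 and the cell cycle gene CKS2 had interactions from 0.40 to 1.10. Each of these 9 had an adjusted p of 1. In all, limma called 0 of 26773 probe sets, with 474 higher and 471 lower at an unadjusted p under 0.05, and the unmoderated model and the trended and robust fit also called 0.

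Interferon response genes had the most positive mean interaction of the called lists, 0.53, with 26 of 27 members above 0, PSMB9 at 0.47 and TAP1 at 0.50. Tested on the mean level of the list per array, this interaction had an absolute t of only 0.84. The list was high on 8 arrays described below, 3 of ISeNTE, 2 of ISeTE, 1 of MIXNTE and 2 of MIXTE. Positive mean interactions were also found for macrophages and dendritic cells (CD163 at 0.54, CTSS at 0.37), T and NK cells (CD8B at 0.37, CD5 at −0.32), class II antigen presentation (BOLA-DQA5 at 0.68, BOLA-DMB at 0.51) and inflammation (LBP at 1.04, CCL5 at 0.40). The same held for the cytosolic ribosome (RPL29 at 0.26, RPSA at 0.21), endoplasmic reticulum stress (PDIA3 at 0.21, MANF at 0.64), heat shock (AHSA1 at 0.23, HSPH1 at 0.58), hypoxia (DDIT4 at 0.47, LDHA at 0.29) and the cell cycle (CENPF at 0.55, MKI67 at 0.56). Camera called these 10 lists with the preset correlation, with adjusted p from 0.000313 to 0.0305, and called 0 with an estimated correlation (smallest adjusted p = 0.802). The interferon interaction was 1.06 in batch 1 and −0.01 in batch 2, and that of endoplasmic reticulum stress −0.04 and 0.26. In the same order the others were 0.42 and 0.01 for macrophages, 0.25 and 0.06 for T and NK cells, 0.31 and 0.09 for class II antigen presentation, 0.18 and 0.07 for inflammation, 0.14 and 0.02 for the ribosome, 0.09 and 0.21 for heat shock, 0.08 and 0.15 for hypoxia and 0.13 and 0.09 for the cell cycle. Without the 2 arrays with little proximal tubule signal the calls of interferon (0.26, adjusted p = 0.091), class II antigen presentation (0.13, adjusted p = 0.235) and macrophages (adjusted p = 0.0546) ended. Of these arrays, ISeNTE replicate 20 was itself high for the interferon list. Without ISeNTE replicate 11 alone, all 10 calls ended (adjusted p from 0.0952 to 0.366). Leaving it out took the interaction from 0.11 to 0.06 for the cell cycle, from 0.13 to 0.06 for inflammation, from 0.22 to 0.10 for macrophages, from 0.15 to 0.10 for T and NK cells and from 0.53 to 0.32 for interferon. Calls also ended with other single arrays left out, for 6 lists with MIXTE replicate 7. Without that array class II antigen presentation fell from 0.20 to 0.10 and T and NK cells to 0.10, and without ISeNTE replicate 10 T and NK cells were at 0.09. The ribosome was at 0.05 without ISeTE replicate 22, against 0.08, endoplasmic reticulum stress at 0.06 without ISeTE replicate 33, against 0.11, and inflammation at 0.07 without ISeNTE replicate 20. The interferon interaction was 0.31 without ISeNTE replicate 20, 0.33 without MIXTE replicate 34 and 0.84 without MIXNTE replicate 25.

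Within single diets and pastures, NXPE2 measured 4.89 ± 0.75 in MIXTE and 3.85 ± 0.20 in ISeTE (SD, n = 8 each), a log2 difference of 1.04. On TE, the values of NXPE3, NEXN, RUBCNL and NUP210L were also higher under MIX, by 0.36 to 0.50. FCMR, ERBB3, ASAP3, MIR495 and DEFB116 were lower by values from −0.55 to −0.26. On NTE, SEMA6A, MIR221, OR1L12, BCAR4 and AHSG were higher under MIX by 0.31 to 0.49, and MIR215, LOC505058, MARCHF1, SCEL and CYTH4 differed by −0.69 to −0.27. Under ISe, SLC19A3 measured 6.64 ± 0.22 on TE and 5.88 ± 0.51 on NTE, and GABBR2, a GABA receptor subunit, 7.42 ± 0.15 and 6.67 ± 0.44. SPIDR, KLHL7 and XPO7 were higher on TE by 0.28 to 0.43, and LOC781494, the sulfotransferase gene SULT1B1, GJC1, MIR2304 and ARPC5L differed by −1.01 to −0.26. Under MIX, RETSAT measured 7.05 ± 0.12 on TE and 7.71 ± 0.27 on NTE, and CKS2 5.55 ± 0.31 and 4.80 ± 0.35. LOC534913, PRR15L, TGM1 and LOC100299732 were higher on TE by 0.30 to 0.55, and SYNGR1, LOC531650, GDF3 and PDCL2 differed by −0.53 to −0.21. Of the other probe sets of LOC531650, 1 of 2 had the opposite sign. Several of these genes were dim. PDCL2, MIR495, MIR2304, OR1L12, BCAR4, SCEL, DEFB116 and MIR215 had means from 2.16 to 3.77 in the groups compared.

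None of these simple effects passed. Limma called 0 probe sets in each of the 4 comparisons, with smallest adjusted p of 0.452 for selenium form on TE, 1 for selenium form on NTE, 0.383 for endophyte under ISe and 0.577 for endophyte under MIX. At an unadjusted p under 0.05 they held 1157, 767, 1551 and 1023 probe sets, in the same order. The unmoderated model, the trended and robust fit and the fits on only the arrays compared called 0 as well. Across 18010 genes, which are not independent replicates, the differences between MIX and ISe on TE and on NTE correlated with r = 0.08, and those between TE and NTE under ISe and under MIX with r = 0.20. These pairs share no arrays.

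Interferon-stimulated genes separated the arrays in every group. On 8 arrays the mean of the 27 measured genes lay 0.76 to 2.02 log2 units above the mean of all 32 arrays, and on the other 24 it lay between −0.80 and −0.10 of it. The antiviral GTPase gene MX1 ranged from 9.29 to 11.24 on the 8 arrays and from 5.76 to 7.88 on the 24. The ubiquitin-like modifier ISG15 ranged from 6.59 to 9.20 and from 4.68 to 5.70. The 8 arrays comprised 3 of ISeNTE, 2 of ISeTE, 1 of MIXNTE and 2 of MIXTE, and 4 came from each batch. The differences given above for this list depended on where these arrays fell and how high each was. Its members rose together on them, so the counts of members given above are not independent support.

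**Figure D4:**
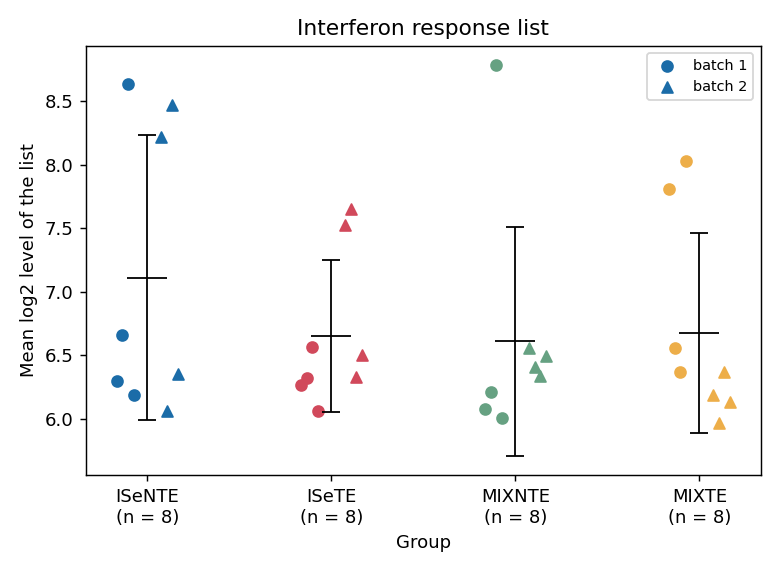
Mean log2 level of the 27 measured interferon response genes (vertical axis) on each array of the 4 groups (horizontal axis). Points are arrays, shapes mark the batches and the bars show the mean ± SD of 8 arrays, with 8 arrays in all lying apart above the rest.

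Between the batches, limma called 20 probe sets, all 20 higher in batch 2 by 0.42 to 0.56 on the log2 scale. None of the 20 had a gene symbol in the annotation used here, and their identifiers ran from 12915652 to 12915703. Of all probe sets, 1399 had an unadjusted p under 0.05 for batch, or 5.23%.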

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

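The tests of the 3 patterns weighed here were chosen after the result was seen, except the correlation of interferon with T and NK cells. An array was singled out when its gap to the nearest of the other 7 arrays of its group exceeded, as a share of the group's range, Dixon's 95% critical value for 8 samples. Chance alone does so in about 1 of 20 groups. It occurred for 43 of 212 groups of list levels (20.3%) and 60 of 660 groups of gene levels (9.09%), and 33 and 26 of these lay on ISeNTE replicate 20 or MIXNTE replicate 32.

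On ISeNTE replicate 20 and MIXNTE replicate 32, the proximal tubule list lay far below the other arrays of its group, with gap shares of 0.896 and 0.828. A low share of cortex in these tissue pieces may account for this, since 8 of 8 comparisons went the way it needs, with podocyte and distal tubule lists below and papilla and principal cell lists above the other 30 arrays. PODXL, a podocyte gene that other cells also express, was 0.32 and 0.15 above the mean of the other 30. Degraded RNA or a failed hybridization is argued against by papilla and principal cell lists above every other array in 4 of 4 comparisons. Non-toxic fescue cannot be told apart from chance, since with 2 of 16 NTE arrays against 0 of 16 TE arrays Fisher's exact test (two-sided) gave p = 0.484, the smallest p that 2 such arrays allow.

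The same 2 arrays stood apart for other lists. On ISeNTE replicate 20 the gap shares of the lowest level were 0.721 for selenoproteins, 0.702 for selenium handling, 0.679 for NRF2 targets, 0.721 for glutathione metabolism, 0.844 for organic ion transporters, 0.654 for ammoniagenesis and 0.759 for amino acid transporters. They were 0.805 for arginine and creatine, 0.709 for endothelin and sodium reabsorption, 0.717 for the prolactin and growth hormone pathway, 0.763 for vitamin D and phosphate, 0.587 for fatty acid oxidation, 0.863 for gluconeogenesis, 0.799 for the distal convoluted tubule and 0.619 for podocytes. On MIXNTE replicate 32 the lowest levels gave 0.727 for selenium handling, 0.803 for glutathione metabolism, 0.862 for organic ion transporters, 0.714 for ammoniagenesis, 0.716 for amino acid transporters and 0.742 for arginine and creatine. They also gave 0.779 for endothelin and sodium reabsorption, 0.661 for prolactin, 0.78 for vitamin D, 0.729 for fatty acid oxidation, 0.788 for gluconeogenesis, 0.817 for the distal convoluted tubule and 0.651 for adipocytes. Its highest levels gave 0.53 for kidney injury markers, 0.677 for papilla and 0.553 for endothelium.

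Among genes on ISeNTE replicate 20, GPX3 was lowest at 10.69 with a gap share of 0.87. The others were DIO1 (0.712), MSRB1 (0.569), SELENOP (0.71), SEPHS2 (0.556), FCMR (0.552), SLC7A9 (0.785), PCK1 (0.789) and KCNJ16 (0.635) at the low end and SELENOW (0.547) at the high end. On MIXNTE replicate 32, DIO1 (0.676), GPX3 (0.759), MSRB1 (0.673), FABP3 (0.599), SLC7A9 (0.766), PCK1 (0.668), SLC8A1 (0.552) and KCNJ16 (0.695) were lowest. NXPE2 (0.601), LOC515333 (0.557), DIO2 (0.609), GPX2 (0.583), AKR1B1 (0.562), S100A4 (0.661), HSPH1 (0.542) and LBP (0.653) were highest there.

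The smooth muscle list was lower on TE by a mean of −0.21 (SE 0.07). The 2 arrays with little proximal tubule signal do not account for it, since it was −0.18 (95% confidence interval −0.33 to −0.02) without them. With the composition covariate it was −0.18 (−0.33 to −0.03). That covariate was −4.48 on ISeNTE replicate 20, −2.92 on MIXNTE replicate 32 and between −0.72 and 1.31 on the others. It thus mainly set those 2 arrays apart, and could not decide whether the share of cortex differed among the others. Chance cannot be excluded, since in 24 of 100 splits of the arrays some list had an absolute t as large as the real 2.81 (highest other 4.50), so an effect of toxic fescue remains a hypothesis.

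The interferon list was high on 8 arrays. A batch difference as the cause is argued against by 4 of the 8 lying in each batch, and selenium form or endophyte as the whole cause by at least 1 lying in every group. More T and NK cells as the whole cause is argued against by 7 of the 8 arrays, whose T and NK list lay at or below the highest of the other 24 (−0.14 to 0.49 on the 8 and −0.27 to 0.44 on the 24, with ISeNTE replicate 20 at −0.14). Still, the T and NK list was high on most of the 8. It exceeded 7 of the other 24 arrays on ISeNTE replicate 20, and 19 to 24 of them on the rest. Whether such cells contribute in part could not be decided. Over the other 24 arrays the 2 lists correlated with r = 0.397 (permutation p = 0.0541, rho = 0.183, p = 0.389, r = 0.25 without the 2 farthest), and over the 8 arrays with r = −0.168 (exact permutation p = 0.687) and rho = −0.238 (exact permutation p = 0.582), and an infection or vaccination of single steers was not tested.

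Further lists had a single array apart, with gap shares of 0.802 for interferon on MIXNTE replicate 25, 0.546 for class II antigen presentation on MIXTE replicate 7, 0.544 for immediate early genes on MIXTE replicate 23, 0.598 for glucocorticoid-induced genes on ISeNTE replicate 5 and 0.551 for the cell cycle on ISeNTE replicate 11. The rest were 0.632 for apoptosis on MIXNTE replicate 26, 0.527 for the proteasome on MIXTE replicate 4, 0.598 for the distal convoluted tubule on ISeTE replicate 33, and 0.628 for neutrophils on both ISeTE replicate 1 and MIXTE replicate 4. Among interferon genes, MIXNTE replicate 25 was highest for OAS1Y (0.641), IFIT2 (0.835), IFIT3 (0.788) and TAP1 (0.603), as well as for ANGPTL4 (0.622), and lowest for TPM2 (0.588). CXCL9 (0.575) was highest on ISeTE replicate 3 and BOLA-DQA5 (0.646) on MIXTE replicate 7.

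On MIXTE replicate 34, GPX1 (0.796), FLOT1 (0.635) and DPAGT1 (0.5263) were lowest and SELENOK (0.585) and RPSA (0.645) highest. On MIXTE replicate 4, MAGEB4 (0.528), MCAM (0.646) and SLC8A1 (0.647) were highest and HADH (0.554) lowest. On ISeTE replicate 6, N6AMT1 (0.557), KLHL7 (0.658) and TXNRD1 (0.639) were highest, and on ISeTE replicate 33, GPX3 (0.602) and TRPV5 (0.555) were lowest. Single arrays also stood apart for GCNT3 (0.527), TMEM131L (0.802), N6AMT1 in MIXTE (0.59), HSF2BP (0.588), ZNF3 (0.587), DEFB116 (0.546), GPX6 in MIXNTE (0.553) and in MIXTE (0.536), NR4A3 (0.583), PDIA4 (0.553), HSP90AB1 (0.612) and PSMC1 (0.572).

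Camera with the preset correlation called an interaction of selenium form and fescue for 10 lists. Adjusted p was 0.000313 for interferon, 0.00304 for macrophages, 0.0128 for the ribosome, endoplasmic reticulum stress, hypoxia and T and NK cells, 0.0139 for heat shock and class II antigen presentation, 0.0266 for inflammation and 0.0305 for the cell cycle, and each was 0.802 with an estimated correlation. For the interferon interaction chance cannot be excluded, with 40 of 100 splits as large, a real t of 0.838 and a highest other of 2.58.

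Chance cannot be excluded for any count of probe sets at unadjusted p or of lists. At adjusted p the splits decide nothing, since the real count was 0 in each comparison and all 100 splits reach that by definition. The highest others were 2 for selenium form, 0 for endophyte, 1 for the interaction, 1 and 5 for selenium form on TE and on NTE, and 2 and 1 for endophyte under ISe and under MIX. At unadjusted p, 75 of 100 splits matched or exceeded 974 for selenium form (highest other 3846), 21 matched 1637 for endophyte (4989) and 72 matched 945 for the interaction (4381). For the simple effects, 41 matched 1157 (2708), 91 matched 767 (5736), 31 matched 1551 (4533) and 62 matched 1023 (2748), in the order used above. For lists, 78 matched 7 (21), 54 matched 10 (24) and 55 matched 10 (21). For the correlations of simple effects, 32 matched 0.0809 (0.431) and 30 matched 0.197 (0.497). Splits with several times the real count may point to a structure of the samples other than the groups, which was not tested.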

How the results depend on the processing

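Leaving out arrays was tried after seeing the data, and the other alternatives were planned. All 7 counts of probe sets stayed at 0 under each of 10 or 11 alternatives, with smallest adjusted p of 0.416 for selenium form, 0.129 for endophyte and 0.134 for the interaction, each with array weights. With single arrays left out they ranged from 0 to 0, except for endophyte, from 0 to 1. The 1 probe set, without a symbol, was called without MIXTE replicate 23 (adjusted p = 0.0465). Unadjusted counts were lowest without the dimmest probe sets, where fewer were tested, and highest with array weights (606 and 1656 for selenium form, 1173 and 2188 for endophyte, 443 and 1203 for the interaction). Among named genes 1821 values kept their direction and 23 reversed, and among list calls, with single arrays left out included, 1015 held, 224 were lost and 8 reversed. The cause was not tested unless stated.

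With an estimated correlation, and with fry, lists called were 0 for selenium form, 0 for endophyte and 0 for the interaction. In batch 2 alone, 21 lists were called for selenium form, and with the composition covariate 16 for the interaction. In batch 1 alone the selenium form difference reversed for fatty acid oxidation (0.014), oxidative phosphorylation (0.0032), interferon (0.35), immediate early genes (−0.081) and smooth muscle (−0.050), and the interaction for endoplasmic reticulum stress (−0.043). ISeNTE replicate 20, an ISe array with little proximal tubule signal, lay in batch 1. Genes that reversed there were CXCL9 (0.46), CXCL10 (0.47), OAS1Y (0.45), CNN1 (−0.0014), TAGLN (−0.022), GPX4 (0.016), TXNRD1 (0.098), SELENOF (0.059), SELENOM (−0.030), SELENON (−0.016), SELENOS (−0.042) and SEPHS2 (0.19). In batch 2 alone the mean interferon interaction reversed (−0.010), while the set test still pointed upward (adjusted p = 0.689). There, DIO1 (−0.28), DIO3 (0.18), GPX3 (−0.15), SELENOK (−0.033), SELENOT (−0.037) and SELENOV (0.028) reversed too. With array weights DIO1 (−0.036) and GPX3 (−0.025) reversed, and with quantile normalization GPX4 (0.0025). Without ISeNTE replicate 20 and MIXNTE replicate 32, DIO1 (−0.029), GPX3 (−0.028) and the proximal tubule list by endophyte (−0.018) reversed, which those 2 arrays caused by construction, and the count for endophyte stayed 0. With single arrays left out, the smooth muscle list by endophyte ranged from −0.25 to −0.18 and the proximal tubule list from 0.15 to 0.43. Dim probe sets, with means up to 5.73, limit what can be read from low genes.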

Other observations

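The alternatives with batches or arrays left out were chosen for these results after they were seen. Some members passed adjustment over their list alone outside the lists described, named after their values were seen. NR5A1, a transcription factor of steroid-making cells in the adrenal cortex list, had a log2 difference of −0.18 between MIX and ISe (limma, adjusted p = 0.0452 over the list alone), and no longer passed with any 1 of 19 arrays left out (adjusted p up to 0.0921). NEFL, a neurofilament gene in the adrenal medulla and nerve list, had an interaction of −0.49 (adjusted p = 0.0204 over the list alone, and up to 0.043 with single arrays left out). Over all probe sets both had an adjusted p of 1.

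For the simple effects, camera with the preset correlation called 4 lists for selenium form on TE, 6 for selenium form on NTE, 8 for endophyte under ISe and 8 for endophyte under MIX. With an estimated correlation it called 0 in each, with smallest adjusted p of 0.842, 0.971, 0.865 and 0.341 in the same order. The 8 lists under ISe were oxidative phosphorylation, interferon, the cell cycle, the proteasome, smooth muscle, T and NK cells and macrophages, each lower on TE, and the proximal tubule, which was higher. On ISeNTE replicate 20 the proximal tubule list was at 7.03, against at least 10.4 on the other ISeNTE arrays. The cell cycle list was at 6.31 on ISeNTE replicate 11 and at most 6.03 on the other ISeNTE arrays. The 8 lists under MIX were the ribosome, endoplasmic reticulum stress, heat shock, hypoxia, the proximal tubule and the distal tubule, each higher on TE, and the proteasome and smooth muscle, which were lower. On MIXNTE replicate 32 the proximal and distal tubule lists were at 7.75 and 7.72, against at least 10.32 and 8.85 on the other MIXNTE arrays. Over both selenium forms, without ISeNTE replicate 20 and MIXNTE replicate 32, the endophyte difference was −0.02 for the proximal and 0.13 for the distal tubule.

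Under ISe alone, markers of macrophages and dendritic cells were lower on TE for 18 of 19 measured, with a mean difference of −0.26 (camera, adjusted p = 1.02e-05, and adjusted p = 0.865 with an estimated correlation). It was −0.31 in batch 1 and −0.21 in batch 2, and −0.14 without ISeNTE replicate 11 (adjusted p = 0.0324). T and NK cell markers were lower for 14 of 20, by a mean of −0.12 (adjusted p = 0.00425, and adjusted p = 0.865 with an estimated correlation), with −0.08 in batch 1 and −0.16 in batch 2. This call ended without ISeNTE replicate 10 (−0.06, adjusted p = 0.171), without ISeNTE replicate 11 (−0.06, adjusted p = 0.109) and without ISeNTE replicate 5 (−0.10, adjusted p = 0.0526). Under MIX the difference was −0.04 for macrophages, lower for 10 of 19 (adjusted p = 0.689), and 0.04 for T and NK cells, higher for 14 of 20 (adjusted p = 0.671). The difference between the 2 selenium forms was called for both lists (interaction, adjusted p = 0.00304 and 0.0128), but not with an estimated correlation (adjusted p = 0.802 for each).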
